A study of Mus musculus with 2 samples.

How the data were processed

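Total RNA from the nuclear fraction of bone marrow-derived macrophages was measured by ribosomal RNA-depleted sequencing in 2 libraries of 1 group. Per the labels, the fraction was nucleoplasmic in the sample description and nuclear in the sample characteristics, library fragments had a size range of 250 to 400, and the starting amount of RNA was 1 µg in replicate 1 and 500 ng in replicate 2, so the input cannot be told apart from the replicate. Replicate numbers were taken from the labels.

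The deposited tables were made on the mouse assembly mm10 with GENCODE annotation M21, per the text files deposited with the samples. For each library the authors deposited a gene table and a transcript table derived from a transcriptome alignment, and a further transcript table derived from the reads directly. The deposited gene and transcript tables hold expected counts, which are estimated reads that need not be whole and are not normalised, per the file headers. Deposited TPM values are such estimates divided by effective length and scaled to the same sum in each library, per the file headers and the values. The deposited isoform percent values of the alignment-based transcript table give the share of a transcript in the TPM of its gene, per the file headers. The further transcript table holds estimated counts and TPM, per the file headers. Column names follow those of RSEM in the alignment-based tables and of kallisto in the other, but the aligner, the quantifiers, their versions and the strand setting are not given in the sources used here. Without a stated strand, reads of overlapping genes on opposite strands may not be separated.

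Gene names, types and positions came from GENCODE M21, in which all 55536 Ensembl genes of the gene tables were found. The tables also hold 26248 entries with numeric identifiers and no gene name, with 24 and 54 expected counts (0.000109% and 0.000303% of all counts), and 97 spike-in entries. These stayed out of all library sizes and comparisons. Where a symbol of a fixed list had 2 identifiers, which was so for 3 symbols, the one with the higher mean TPM was used. All 369 symbols of the lists were matched.

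Depth was 21954179 and 17739520 expected counts in genes. The limit for a count of 0 was set at 3 counts, and shares of counts in a single library carry 95% Wilson intervals. Reads are not independent molecules, so both cover counting error only. Values are given as the mean and SD of the 2 libraries. Levels were taken as log2(mean TPM + 1), and the difference between libraries as log2 of replicate 2 over replicate 1 after adding 1 to each TPM, minus its median over genes with a mean TPM of 1 or more. A fold on this scale understates that of low genes. With 1 library on each side no test between the libraries is possible, so gene lists were described by the percentile of their median among 10000 random lists of the same size. For levels these were drawn from genes with a mean TPM of 1 or more, and for differences they were matched on expression in 20 bins and needed at least 3 list members at that level. Lists beyond percentile 2.5 or 97.5 were counted. Pairs of lists were compared by two-sided permutation tests of the difference in medians with 100000 resamples. A chi-square test of rounded expected counts, over genes with at least 10 in each library, checked whether the libraries could be a single library deposited again. No pairing applied, as there was 1 group.

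The 25 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where an alternative is said to have been chosen later. The rule named the 3 members with the highest mean TPM of each list, 19 genes of the macrophage response and nuclear RNA in every case, and the 10 genes with the highest mean TPM. Between libraries it named the 5 genes with the most extreme differences in each direction, with at least 100 expected counts in the 2 libraries together, and up to 3 genes per list that differed over 2-fold. For isoforms it named transcripts of Neat1 and Malat1 at 1 TPM or more in both libraries.

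Alternatives were pseudocounts of 0.1 and 5, no filter, a minimum of 10 counts in each library, TPM rescaled without mitochondrial genes and genes under 200 bases, the other transcript table summed to genes, no centring, TMM-scaled counts, counts not divided by length, and leaving out each replicate. Added after seeing the data were protein-coding genes alone and removal of the running trend of the difference, over 50 bins, on transcript length or GC content. TMM factors for the rounded expected counts came from edgeR 4.0.16 in R 4.3.3. The other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

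The list procedure was tested on simulated data with the 12952 genes of the comparison between libraries. Lists of 20 genes shifted by 0.5 on the log2 scale were called in 90% of 20 rounds and those shifted by 1 in 100%, with mean recovered shifts of 0.35 and 0.87, and 5.5% of 200 unchanged lists were called. The simulated noise was independent between genes, so trends shared by the genes of a list were not covered. The permutation test on 36 simulated genes gave a p under 0.05 in 6% of 200 rounds with no difference.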

Results

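Ribosomal RNA-depleted total RNA was sequenced from the nuclear fraction of bone marrow-derived macrophages, which are primary phagocytes grown from mouse bone marrow, here of the C57BL/6J strain. The cells had been exposed to 100 ng/ml Lipid A, the part of bacterial lipopolysaccharide that TLR4 recognises, for 12 hours. They were then kept without it for 12 hours and stimulated with the same concentration for 20 minutes. The design held 1 group with 2 libraries, labelled biological replicates 1 and 2, which carry the same donor label, and the recorded RNA input was 1 µg for replicate 1 and 500 ng for replicate 2. Whether the cultures came from separate animals is not given in the sources used here. The gene tables held 21954179 expected counts in replicate 1 and 17739520 in replicate 2, and a gene with 0 counts could still reach 0.137 and 0.169 CPM, the usual scaling of counts to a common library total, in the 2 libraries. These limits, and the binomial intervals given below, cover counting error only. No naive or unstimulated library was part of the group, so levels were compared with the rest of the transcriptome, between fixed gene lists and between the 2 libraries, and no response to stimulation was measured.

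A few nuclear noncoding transcripts took a large share of the counts. Malat1 (ENSMUSG00000092341.3), a long noncoding RNA of nuclear speckles, took 10.5% ± 0.0442 (SD, n = 2) of the expected counts, and the 18 nuclear-retained long noncoding RNAs of the fixed list took 11.4% ± 0.195 (SD, n = 2) together. Neat1, the RNA scaffold of paraspeckles, had 867 ± 16.5 TPM (SD, n = 2), and Xist, the RNA that coats the inactive X chromosome, had 82.1 TPM in replicate 1 and 196 TPM in replicate 2. The 13 mRNAs of the mitochondrial genome took 4.89% ± 2.03 (SD, n = 2) of the counts. The highest count of any of them was that of mt-Co1, with 387906 in replicate 1 and 511747 in replicate 2 and 14282 ± 6440 TPM (SD, n = 2). The short mt-Atp8 had 6437 and 35616 TPM on 4602 and 13888 counts, and mt-Nd6 had 5312 ± 1736 TPM (SD, n = 2). The share of the mitochondrial mRNAs was 3.45% in replicate 1 (95% Wilson interval 3.44 to 3.46) and 6.32% in replicate 2 (6.31 to 6.33), while the long noncoding list stayed at 11.3% (11.2 to 11.3) and 11.5% (11.5 to 11.5) of counts. By summed TPM both were higher in replicate 2, with 17470 and 29429 for the long noncoding list and 32869 and 89701 for the mitochondrial mRNAs. These sums leaned on short entries. Malat1 had 16332 and 28092 TPM, while its share of counts was 10.5% and 10.6%. Its 485-base transcript had 5091 and 15172 TPM, against 11156 and 12915 TPM for its 6983-base transcript. The short mt-Atp8 held a large part of the mitochondrial rise. Protein-coding genes held 76.8% ± 1.08 (SD, n = 2) of the counts but 29.5% ± 5.70 of the TPM, because TPM divides by length. Rn7sk, the short RNA that holds the elongation factor P-TEFb inactive, had 268806 ± 387 TPM (SD, n = 2), or 26.9% of all TPM, on 4.05% ± 0.650 of the counts.

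**Figure D1:**
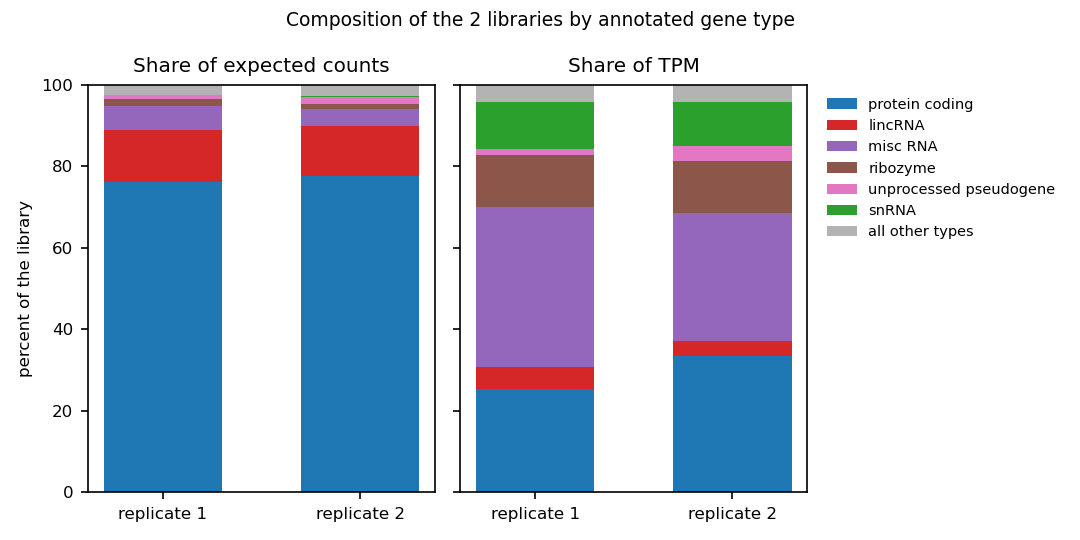
Stacked bars give the percent of each library's expected counts (left) and TPM (right) in annotated gene types, 1 bar per replicate. Protein-coding genes take 76.1% and 77.6% of the counts but 25.5% and 33.5% of the TPM, where misc RNA, which includes Rn7sk, takes 39.2% and 31.4%.

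The 10 highest genes by TPM were Rn7sk, Rpph1, both annotated entries of Rmrp, Rn7s1, Rn7s2, Malat1, mt-Atp8, Gm22513 and mt-Co1. Rpph1, the RNA of ribonuclease P, had 77305 ± 6125 TPM (SD, n = 2). Rmrp, the RNA of ribonuclease MRP, had 50953 ± 6752 TPM in its ribozyme entry and 17398 ± 20192 TPM in an overlapping long noncoding entry. Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, were listed with the same 41707 ± 27130 TPM. Gm22513, a small nuclear RNA gene, had 15096 ± 787 TPM on 3463 and 1642 counts in replicates 1 and 2. By contrast, mt-Co1 had 387906 and 511747 counts at a similar TPM, so the rank of Gm22513 reflects division by its short length. Reads of Rn7s1 and Rn7s2, of the Rmrp pair and of overlapping mitochondrial genes cannot be assigned to a single entry with certainty, so their values are uncertain.

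Interferon-stimulated and macrophage identity genes stood far above the typical gene. All 24 interferon-stimulated genes reached 1 TPM, 17 of them reached 100 TPM, and the list's median was 148 TPM (160 in replicate 1 and 120 in replicate 2). Rsad2, which encodes the antiviral enzyme viperin (ENSMUSG00000020641.16, chromosome 12, 26442746 to 26456452, mm10), had 948 ± 397 TPM (SD, n = 2), Ifit2 had 814 ± 19.9 TPM and Mx1 had 704 ± 303 TPM. Cxcl10, a chemokine induced by interferon (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), had 300 ± 188 TPM (SD, n = 2). Of the 23 macrophage genes 22 reached 1 TPM, with a median of 111 TPM. The lysosomal proteases Ctsb and Ctsd had 1551 ± 146 and 1496 ± 2.23 TPM, and the lysozyme gene Lyz2 had 1411 ± 254 TPM (SD, n = 2). Both medians lay above those of all 10000 random lists of the same size drawn from the 12952 genes with a mean TPM of 1 or more, which describes these libraries and is not a test.

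Immediate early, NF-kB feedback and TLR4 signalling genes also had high list medians. The 24 immediate early genes had a median of 26.7 TPM, at percentile 99.99 of random lists, with 21 genes at 1 TPM or more. Egr2, Egr3 and Klf4, named after their values were seen, were under it at 0.980, 0.350 and 0.495 TPM. Zfp36, which encodes an mRNA-destabilising protein (chromosome 7, 28376784 to 28380253), had 218 ± 10.8 TPM (SD, n = 2), the AP-1 subunit gene Junb had 129 ± 45.9 TPM and the transcription factor gene Klf6 had 118 ± 2.81 TPM. Fos had 20.8 TPM in replicate 1 and 78.3 TPM in replicate 2, and Egr1 had 21.5 ± 8.39 TPM (SD, n = 2). All 20 NF-kB subunit, inhibitor and feedback genes reached 1 TPM, with a median of 19.4 TPM at percentile 99.71. They were led by Nfkbia, the gene of the inhibitor IkBα (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647), with 146 ± 50.9 TPM (SD, n = 2), Tnip3 with 117 ± 5.17 TPM and Tnfaip3, the gene of the deubiquitinase A20, with 79.8 ± 0.629 TPM. The 23 genes of TLR4 signalling had a median of 23.5 TPM at percentile 99.98. Tlr4 itself had 27.6 ± 5.32 TPM (SD, n = 2), its co-receptor gene Cd14 had 92.5 ± 27.2 TPM, and the kinase genes Ikbke and Tbk1 had 307 ± 54.2 and 55.2 ± 5.18 TPM.

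**Figure D2:**
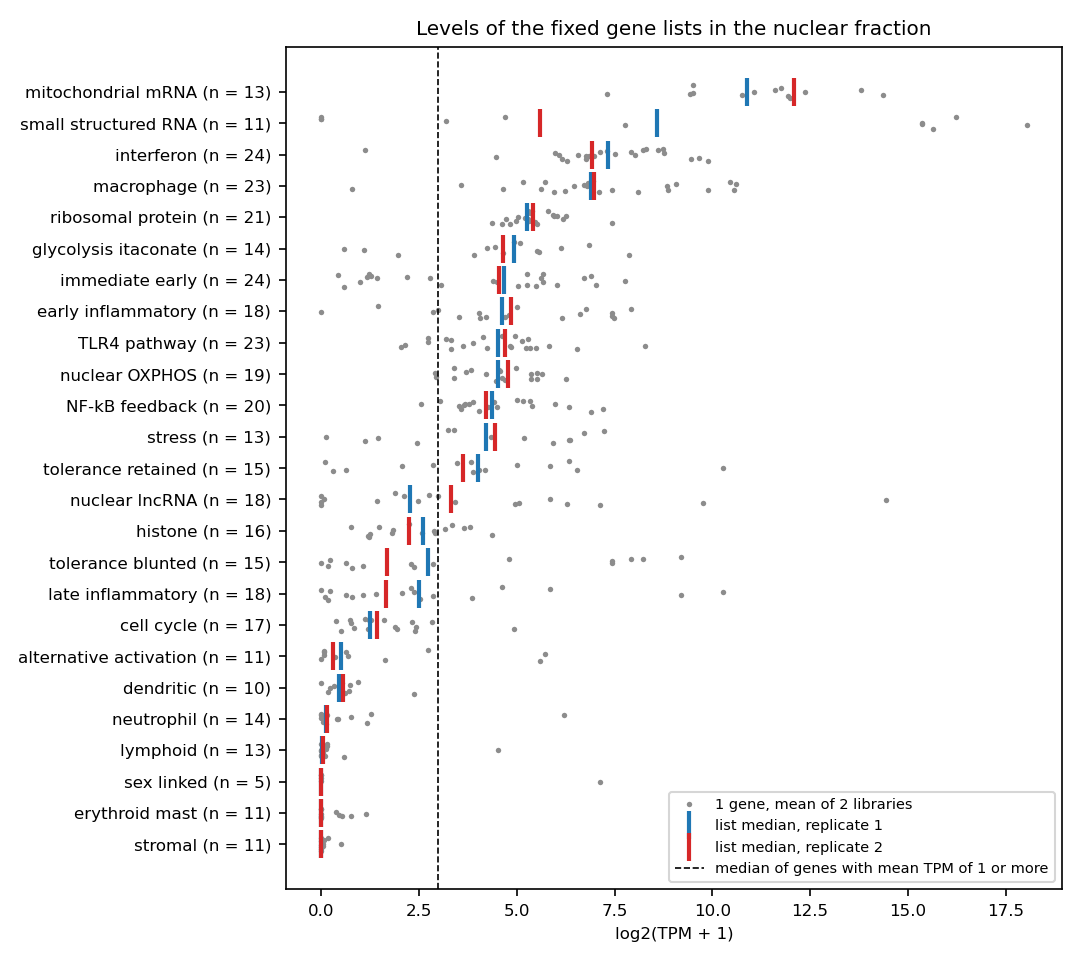
Each grey point is the log2(mean TPM + 1) of a gene in a fixed list, the blue and red ticks are the list medians in replicates 1 and 2, and the dashed line is the median of the 12952 genes with a mean TPM of 1 or more. Interferon-stimulated and macrophage genes lie far to the right of the line, with medians of 148 and 111 TPM, and the stromal and erythroid or mast cell lists lie at 0.

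Among housekeeping and metabolic lists, the 21 ribosomal protein mRNAs had a median of 39.6 TPM above all random lists and were led by Rps24 with 173 ± 56.3 TPM (SD, n = 2), Rpl3 with 75.4 ± 0.841 TPM and Rpl13a with 71.7 ± 14.2 TPM. The 19 nuclear-encoded oxidative phosphorylation genes had a median of 22.7 TPM at percentile 99.93, with Atp5b at 75.5 ± 14.2 TPM, Sdha at 49.2 ± 8.58 TPM and Cox7c at 44.7 ± 10.5 TPM. Acod1, the enzyme that makes itaconate (chromosome 14, 103046977 to 103056573), had 233 ± 108 TPM (SD, n = 2), and it led the 14 glycolysis and itaconate genes, whose median of 26.8 TPM lay at percentile 99.95, before Pkm with 113 ± 1.12 TPM and Gapdh with 68.5 ± 1.26 TPM. The 13 stress genes had a median of 19.1 TPM at percentile 98.56. Of these, Hspa5, a chaperone of the endoplasmic reticulum, had 150 ± 43.9 TPM, the peroxiredoxin gene Prdx1 had 105 ± 20.4 TPM and Sod2, the mitochondrial superoxide dismutase, had 81.4 ± 25.8 TPM. The mitochondrial list, with a median of 3100 TPM (1882 in replicate 1 and 4353 in replicate 2), and the small structured RNA list, with 216 TPM (385 and 47.5), also lay above all random lists. With counts that were not divided by length, the small structured RNAs lay at percentile 0.09, the ribosomal protein mRNAs at 93.6 and the nuclear-encoded oxidative phosphorylation genes at 73.4, so these 3 high levels depended on the TPM scale.

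Markers of other cell types were near 0. The median was 0.0975 TPM for 14 neutrophil and precursor genes, 0.480 TPM for 10 dendritic cell genes, 0.0250 TPM for 13 lymphoid genes and 0 TPM for 11 stromal and for 11 erythroid or mast cell genes. The random lists held only genes with a mean TPM of 1 or more, so medians under that level fall below all of them by construction. A few members stood apart: Csf3r, the receptor for granulocyte colony-stimulating factor, had 72.8 ± 7.82 TPM (SD, n = 2) and the coreceptor gene Cd4 had 22.1 ± 9.86 TPM. S100a9 had 1.42 ± 0.587 TPM, Batf3 had 4.20 ± 1.73 TPM and Acta2 had 0.430 ± 0.424 TPM. The erythroid gene Alas2 had 1.20 ± 0.750 TPM, and the mast and progenitor cell gene Kit had 0.705 ± 0.318 TPM. The 4 Y-linked genes, among them Ddx3y and Eif2s3y, were at 0 in both libraries, so the sex-linked list with Xist had a median of 0. The labels do not give the sex, but these values, with Xist at 82.1 and 196 TPM, argue against male cells. The 17 cell cycle genes had a median of 1.42 TPM, with Pcna, the DNA polymerase clamp, at 29.6 ± 8.91 TPM, and the 11 genes of alternative activation had a median of 0.545 TPM, with the mannose receptor gene Mrc1 at 52.2 ± 32.2 TPM and Il4ra at 47.1 ± 14.7 TPM. The median of 16 histone genes, 4.33 TPM, lay inside the range of random lists at percentile 12.1, with Hist1h1c highest at 19.6 ± 3.59 TPM. The median of the 18 nuclear long noncoding RNAs, 6.34 TPM, lay inside it at percentile 40.5, since a few RNAs carried that list. Against all genes with any value, the dendritic, cell cycle and alternative activation lists lay inside the range too, at percentiles 11.6, 38.8 and 14.5, and with counts not divided by length or in the other table the histone list lay below it, at 0.07 and 0.03.

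Inflammatory genes that are usually transcribed early after TLR4 stimulation were compared with those usually transcribed late, because the stimulation lasted 20 minutes. The early genes stood higher, with a median of 25.8 TPM over 18 genes against 3.55 TPM over 18 late genes. Among the early genes, Tnf, which encodes a central inflammatory cytokine (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), had 240 ± 122 TPM (SD, n = 2), and the chemokine genes Ccl7, Ccl4, Ccl3 and Cxcl2 had 178 ± 54.2, 171 ± 109, 171 ± 27.6 and 70.8 ± 3.95 TPM. Il1b had 26.7 ± 1.26 TPM and Il10, an anti-inflammatory cytokine gene, had 15.5 ± 0.0495 TPM. Other early genes were far lower, such as Cxcl1 at 6.93 TPM and Cxcl3 at 0.005 TPM, both named after their values were seen. The wide spread was thus a trait of both lists. Late genes were spread widely, with Il12b at 0.725 ± 0.0636 TPM, Il6 at 1.08 ± 0.255 TPM and Nos2, the inducible nitric oxide synthase, at 4.21 ± 3.01 TPM against the acute phase gene Saa3 (chromosome 7, 46711998 to 46715700) at 1235 ± 720 TPM and the chemokine gene Ccl5 (chromosome 11, 83525778 to 83530518) at 589 ± 327 TPM. The scavenger receptor gene Marco had 56.7 ± 22.2 TPM. The medians differed by 2.56 on the log2(TPM + 1) scale, or 5.89-fold, in a two-sided permutation test across genes (p = 0.0115, Benjamini-Hochberg adjusted over 2 such comparisons 0.0230). The size of the difference was 9.17-fold with replicate 2 alone, 4.38-fold with replicate 1 alone and 10.03-fold with counts not divided by length. Genes are not independent replicates, and the test compared levels of different genes in cells exposed to the ligand on 2 occasions, not a change over time.

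Genes commonly described as retained or raised in endotoxin-tolerant macrophages were compared with those described as blunted, because the cells had met the same ligand before. No difference between these lists passed the test. The 15 retained genes had a median of 13.8 TPM and included Saa3, Cd14, Tnfaip3 and Il1rn, the gene of the interleukin-1 receptor antagonist, which had 13.3 ± 2.62 TPM (SD, n = 2). The 15 blunted genes had a median of 4.21 TPM and included Il6 and Il12b near 1 TPM as well as Ccl5, Cxcl10 and Tnf at 240 TPM or more. The medians were 3.88 and 2.38 on the log2(TPM + 1) scale, a 2.84-fold difference (two-sided permutation test across genes, p = 0.300, adjusted 0.300), and the log2 difference was 0.07 with counts that were not divided by length (permutation p = 1). Compared with random lists, the late, blunted and retained medians lay inside the range, at percentiles 4.06, 12.3 and 94.9, but with replicate 2 alone the late and blunted lists lay below it, with medians of 2.14 and 2.20 TPM at percentiles 0.07 and 0.155. The late list also lay below it with counts not divided by length, at 0.36, and in the other table, at 0.9, and the retained list lay above it at 99.8 against all genes with any value.

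The 2 libraries were then compared with each other, since they are the only replicates, with each difference taken relative to the median gene. Interferon-stimulated and late inflammatory genes were lower in replicate 2 and mitochondrial mRNA was higher there. All 24 interferon-stimulated genes were lower, 9 of them over 2-fold, with a median log2 difference of -0.85 (SD over genes 0.51) against a central 95% of -0.42 to 0.07 in random lists matched on expression, and without centring 22 of them were lower with a median of -0.56. Isg15, a ubiquitin-like modifier gene, differed by -1.93, Isg20 by -1.87 and Cxcl10 by -1.66. All 12 late inflammatory genes that reached 1 TPM were lower, with a median of -1.23 (SD 0.39), among them the siderophore-binding gene Lcn2 at -1.65, Saa3 at -1.55 and Nos2 at -1.54. The blunted and retained tolerance lists, which share genes with these, had medians of -1.35 (SD 0.67, 9 of 10 genes lower) and -0.90 (SD 0.66, 11 of 12 lower), and Fpr1, a formyl peptide receptor gene of the retained list, differed by -1.67. Of 20 NF-kB feedback genes 18 were lower, with a median of -0.69 (SD 0.52), including Socs1 at -1.73, Socs3 at -1.48 and Traf1 at -1.07.

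Other lists that were lower in replicate 2 were the histone genes, with a median of -0.66 (SD 0.48, 15 of 15 lower), the glycolysis and itaconate genes at -0.44 (SD 0.35, 12 of 13), the stress genes at -0.45 (SD 0.58, 9 of 12) and the ribosomal protein mRNAs at -0.38 (SD 0.44, 17 of 21). Without centring these 4 lists had medians of -0.37 (13 of 15 lower), -0.15 (8 of 13), -0.16 (8 of 12) and -0.09 (12 of 21), the NF-kB feedback list had -0.40 (15 of 20) and the nuclear long noncoding list had 0.63. Immediate early genes had a median of -0.40 (SD 0.76, 16 of 21 lower, or -0.11 with 14 lower without centring), but their members went both ways, with Gadd45b at -1.30, Egr1 at -1.07 and Junb at -1.02 against Fos at 1.57 and Fosb at 1.38. Small structured RNAs had a median of -1.72 (SD 1.94, 8 of 8), which is the value of Rn7s1 and Rn7s2. Among them Rnu12, with 48 and 3 counts, and Vaultrc5, with 4 and 0, lay near the limit of counting and were named after their values were seen. Mitochondrial mRNAs were higher, with a median of 0.94 (SD 0.76, 11 of 13 higher), including mt-Atp8 at 2.18, mt-Nd2 at 1.42 and mt-Nd1 at 1.34, and so were nuclear long noncoding RNAs at 0.34 (SD 0.53, 11 of 14), including Snhg14 at 1.16 although Mir155hg differed by -1.02. The early inflammatory list, with a median of -0.29, or -0.01 without centring, stayed inside the matched range at percentile 6.62 although Ccl4, Tnf and Ccl2 differed by -1.69, -1.37 and -1.31. The macrophage list at -0.24, with Cebpb at -1.97, Fcgr1 at -1.04 and Mrc1 at 1.03, and the TLR4 list at -0.04 were inside it as well, and without centring their medians were 0.05 and 0.25. Also inside were the nuclear-encoded oxidative phosphorylation list at -0.10 and the cell cycle list at -0.03, which were 0.19 and 0.26 without centring, the alternative activation list at 0.23 and the neutrophil list at 0.17. In all, 11 lists were lower and 2 higher of 20 compared. About 1 outside the range would arise by chance if lists, and the genes within each, varied independently. Genes of a list can share a trend, such as that on GC content below, so the figure is no measure of chance here. 28 genes stood in more than 1 list.

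**Figure D3:**
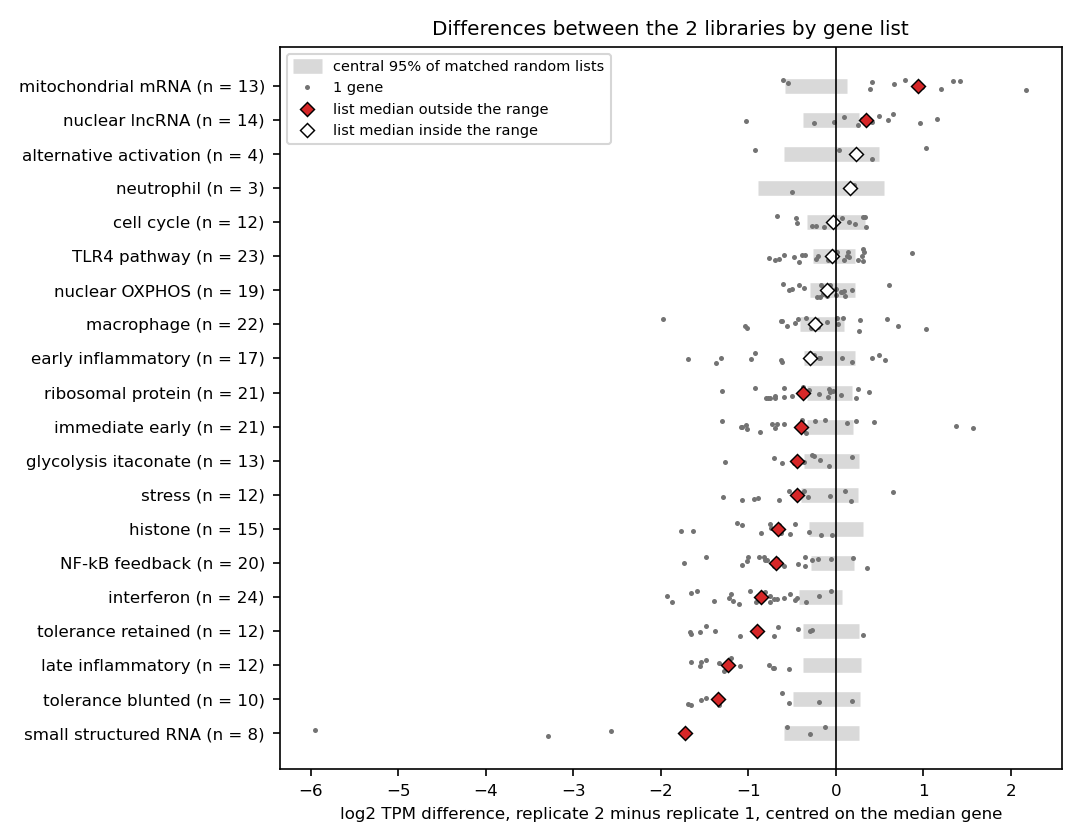
For each list, grey points are genes with a mean TPM of 1 or more, the diamond is the list median of the log2 TPM difference (replicate 2 minus replicate 1, centred on the median gene), and the grey bar spans the central 95% of medians of matched random lists. Late inflammatory, blunted and retained tolerance and interferon-stimulated genes lie to the left of their bars, with medians of -1.23, -1.35, -0.90 and -0.85, and mitochondrial mRNAs lie to the right with 0.94.

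The differences followed GC content across genes (Spearman rho -0.51 over 12942 genes, which are not independent replicates). With that trend removed, an alternative chosen after seeing the data, the interferon list had -0.85, the late list -1.11 and the blunted list -1.28, while the NF-kB feedback median was -0.45, the nuclear long noncoding median 0.19 (9 of 14 higher, percentile 97.67), the mitochondrial median 0.33, and the immediate early, stress and glycolysis lists lay inside their ranges at percentiles 8.04, 5.64 and 7.62. The early inflammatory list then lay below its range, with a median of -0.31 at percentile 2.39. With the trend on transcript length removed, also chosen after seeing the data, the ribosomal protein and stress lists lay inside their ranges at -0.29 and -0.34, and in the other table so did the nuclear long noncoding and small structured RNAs at 0.42 and -0.17.

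Single genes with the most extreme differences were mostly small RNAs and pseudogenes. The U3 small nucleolar RNA genes Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 were listed at 180 TPM in replicate 1 and at 0 in replicate 2, and Rnu3a at 141 TPM and 0. In the other direction stood the small nuclear RNA genes Gm24924, at 0 and 3183 TPM, and Gm24497, at 20.8 and 3199 TPM, the antisense gene Gm47248 at 0 and 19.6 TPM, the pseudogene Rps6-ps4 at 0.5 and 19.8 TPM, and the zinc finger gene Zfp993 at 14.2 and 86.4 TPM. Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 had the same value, so reads cannot be placed among these 4 with certainty, and reads shared with other copies were not examined for the rest. Over all 12952 genes the Spearman correlation between the libraries was 0.907 and Pearson's r of log2(TPM + 1) was 0.914, both across genes, which are not independent replicates. The median gene was 0.29 higher on the log2 scale in replicate 2, and about that value the median size of a difference was 0.32, or 1.25-fold. The number of genes differing over 2-fold between the libraries was 944 (7.29%), 360 higher and 584 lower in replicate 2, but without centring 919 were higher and 330 lower. Expected counts of 14347 genes differed by far more than sampling noise (chi-square per degree of freedom 91.3), so the tables are not a single library deposited again, which leaves open whether the cultures were separate. In both libraries 11776 genes reached 1 TPM.

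At the level of isoforms, the short 3004-base transcript held 87.2% ± 0.856 (SD, n = 2) of Neat1 TPM and the long transcript of 20771 bases, on which paraspeckles are built, held 9.07% ± 0.834. Their levels were 757 ± 6.97 and 78.8 ± 8.77 TPM, and transcripts of 1030 and 711 bases held 2.90% ± 0.382 and 0.795% ± 0.361. Both Neat1 and Malat1 lie on chromosome 19, at 5824708 to 5845478 and 5795690 to 5802672. Malat1 was divided between a transcript of 6983 bases with 57.1% ± 15.8 and one of 485 bases with 42.6% ± 16.2 of its TPM, with a transcript of 556 bases at 0.0300% ± 0.0141. A share of TPM weights the shorter transcript strongly. Between the deposited transcript tables, the Spearman correlation across 37801 transcripts was 0.527 in replicate 1 and 0.409 in replicate 2. Summed to genes, it was 0.933 and 0.905 over 12952 genes, and 0.963 and 0.947 over 10050 protein-coding genes.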

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

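All tests of the mitochondrial pattern below, and the comparison with cytoplasmic mRNA for the interferon list, were chosen only after the results were seen.

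Reads of the phiX174 control genome, which is added to sequencing runs and lies outside the gene comparisons, took 0.581% of all expected counts in replicate 1 (95% Wilson interval 0.578 to 0.584) and 0.434% in replicate 2 (0.431 to 0.437), far above the limit that a count of 0 allows. All 96 ERCC spike-in entries were at 0 in both libraries.

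Interferon-stimulated genes were lower in replicate 2 by a median of -0.85 on the log2 scale, together with late inflammatory genes. A technical trend on transcript length or GC content is argued against as the whole cause for the interferon list, whose median was -0.80 and -0.85 after removing each, still below all matched random lists. The choice of quantifier is argued against too, with -0.64 in the other transcript table. Less cytoplasmic RNA in replicate 2 is not settled by these values. The list lay -0.68 below ribosomal protein and nuclear-encoded oxidative phosphorylation mRNA (24 and 40 genes, 1 library on each side). However, mRNAs need not all have the same cytoplasmic share. Ribosomal protein mRNA was lower at -0.38 and nuclear long noncoding RNA higher at 0.34, while oxidative phosphorylation mRNA lay inside its range at -0.10. RNA input, which was 1 µg and 500 ng, differs exactly as the replicates do, so it may contribute and was not tested. With a single group, no biological explanation was tested either.

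Mitochondrial mRNA was higher in replicate 2 by a median of 0.94 (SD over genes 0.76). Reads shifting between the mitochondrial genome and its nuclear pseudogene copies are argued against, since the sum of both was 1.14 higher and all 7 pseudogenes were higher, with a median of 1.01. More cytoplasmic RNA in replicate 2 is not settled by these values. Ribosomal protein and nuclear-encoded oxidative phosphorylation mRNAs had a median of -0.18 relative to the median gene. The median gene was itself 0.29 higher in replicate 2, and centring removes a rise that most mRNAs share. In addition, mRNAs need not all have the same cytoplasmic share. That comparison runs across genes with 1 library on each side, so it is a description of these libraries. Mitochondrial mRNAs have a median GC content of 37.1% against 48.4% for all compared genes. Removing the GC trend left 0.33 (bootstrap SD 0.172, 9 of 13 higher), above the 0.11 that bounds matched lists, so GC content could account for much of this difference. Whether it accounts for all of it is not settled, because the bootstrap SD is large beside what was left. The matched lists were also matched on expression and not on GC content. A different amount of mitochondria carried into the nuclear fraction may remain as a candidate explanation, which was not tested, and no biological explanation was tested.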

How the results depend on the processing

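The alternatives limited to protein-coding genes or with a trend on length or GC content removed were chosen after seeing the data, and the cause of the shifts below was not tested. The Spearman correlation between the libraries of 0.907 was 0.918 with no filter, 0.959 with at least 10 counts, 0.928 with rescaled TPM, 0.875 in the other table and 0.949 in protein-coding genes. The median size of a difference, 0.324, was 0.388 and 0.202 with pseudocounts of 0.1 and 5, 0.260 with no filter, 0.287 with at least 10 counts, 0.330 rescaled, 0.305 in the other table, 0.409 uncentred, 0.297 in protein-coding genes, and 0.315 and 0.252 without the trend on length and GC content. Genes differing over 2-fold between the libraries, 944, became 1661 and 306 with pseudocounts of 0.1 and 5, 581 with at least 10 counts and 407 in protein-coding genes. Of these genes differing over 2-fold between the libraries 38.1% were higher in replicate 2, against 56.2% with no filter, 64.4% in the other table and 73.6% uncentred. The long noncoding share of 11.4% of counts was 2.35% of TPM, where short RNAs weigh more by construction. The correlation of the transcript tables, on average 0.468, was 0.350 at 10 TPM or more and 0.565 at 200 bases or more.

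No called list, and no gene named for its difference, changed sign under any alternative run. Between 18 and 22 lists had a high or low level, against 20, and 11 to 13 differed between the libraries. In the main setting a list median under 1 TPM counted as low by construction. The early list exceeded the late list by 1.85 to 3.33 on the log2 scale, with permutation p between 0.00595 and 0.0224, and the difference between the tolerance lists, 1.05-fold to 3.89-fold, passed the test in none of the settings run (permutation p from 0.283 to 1). The small structured RNA list lay inside the matched range in the other table (-0.17) and with at least 10 counts (-0.53), and the stress list with no filter (-0.20). Late, blunted and retained list medians, -1.23, -1.35 and -0.90, were -0.60, -0.41 and -0.50 with no filter and -0.71, -0.79 and -0.70 with a pseudocount of 5, still below their ranges. The median gene, 0.29 higher in replicate 2, was 1.28 higher in the other table, 0.37 higher after rescaling, 0.12 higher with no filter and 0.03 lower with TMM, so differences are relative to that gene. Levels of named genes depended on the table: 70 moved by more than the SD of the libraries in the other table and 14 did not, and after rescaling, which raises TPM by construction, 35 did and 45 did not. Depth limits short genes even at high TPM, such as Rnu12 with 47.5 TPM on 3 counts in replicate 2, a gene chosen after its values were seen. No paired analysis was possible because there was 1 group.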

Other observations

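The tests of retained-intron shares in the immediate early and early inflammatory lists were planned before their results were seen, and the other values here were chosen after.

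Transcripts annotated as retained introns took 9.54% ± 1.09 (SD, n = 2) of the transcript-level expected counts, against 64.0% ± 0.0695 for protein-coding transcripts. Over 6225 protein-coding genes with such an isoform the median share was 14.3% in replicate 1 and 16.2% in replicate 2. Macrophage identity genes had low shares, with a median over 9 genes of 2.59% and 1.54% at percentiles 1.27 and 0.205 of matched lists. Ctsd had 0.292% ± 0.0950 and Ctsb had 2.37% ± 0.443 (SD, n = 2), but Mrc1 had 12.2% ± 10.3, and Msr1 and Trem2, named after their values were seen, had 25.9% ± 0.935 and 60.6% ± 4.65. The 4 alternative activation genes with such an isoform, which also include Mrc1, had medians of 2.11% and 1.75% at percentiles 2.02 and 1.98. Interferon-stimulated genes had higher shares, with a median over 15 genes of 30.1% and 28.7% at percentiles 96.2 and 90.8, inside the range of matched lists in both libraries. Cxcl10 had 30.6% ± 2.61, and Irf7, a regulator of interferon genes, had 58.5% ± 2.44 and was named after its value was seen.

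A hypothesis was that genes transcribed soon after stimulation would carry unspliced RNA in this fraction and so show a high retained-intron share. Neither list met it. The labels call the fraction both nucleoplasmic and nuclear, and whether chromatin, where nascent RNA is held, was removed is not given in the sources used here, so these shares leave unspliced RNA on chromatin untested. The shares also count only isoforms annotated as retained intron, in genes that have such an isoform. Other unspliced RNA, on chromatin or not, was therefore not tested. The 8 early inflammatory genes with such an isoform had a median of 27.8% and 34.7%, against 14.7% and 17.2% in matched lists. The lower of their percentiles among matched lists was 90.2. The 6 immediate early genes had 11.5% and 9.0%, against 15.3% and 17.2% in matched lists, with a lower percentile of 20.9. Whether lists this small could show a higher share was not tested, so the early list's result does not exclude one. Single genes varied widely, with Cxcl2 at 66.6% ± 3.34, Il1b at 19.6% and 16.4% in the 2 libraries, Cd83 at 86.7% ± 1.46 and Klf6 at 1.31% ± 1.20 (SD, n = 2), of which Cd83 was named after its value was seen.

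The 2 quantifications ranked the libraries differently in total. The other transcript table held 30.3 M estimated counts in replicate 1 and 31.4 M in replicate 2, while the gene table held 21954179 and 17739520. In that table the 57-base miRNA entries Gm24245, Gm24270 and Gm23935 were listed with 193820 TPM each in replicate 1 and 65510 TPM in replicate 2, and miRNA entries took 58.8% and 22.7% of its TPM. In the alignment-based transcript table miRNA entries took 0.00799% and 0.00157% of TPM. The pseudogene entries Gm12895 and Gm12896 had 104665 and 111203 TPM each in that other table.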
